A study of Mus musculus with 6 samples.

How the data were processed

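Total RNA from 6 samples of fluorescence-sorted intestinal cells was measured, 3 of CCK-EGFP cells and 3 of non-fluorescent cells from CCK-EGFP transgenic Swiss Webster mice. Per the labels' protocols, the intestine was dissociated with enzymes, cells were purified by sorting, RNA was extracted with a column kit for small samples, and picogram amounts were amplified with a whole-transcriptome kit and labelled with biotin. The authors deposited 1 table of 45101 probe sets, and per the submitters' processing notes its values come from RMA, which corrects background, normalizes quantiles between arrays and summarises the probes of a set. The RMA version and options are not given in the sources used here. The deposited values run from 1.47 to 14.8 and were taken as log2, the scale on which RMA reports. Quantile normalization acts to make the distributions of all arrays alike, so a broad shift of expression between the groups can be reduced. The deposited distributions still differed, with array medians of 5.66 to 5.72 in CCK-EGFP cells and 5.37 to 5.55 in non-EGFP cells. Amplification from picograms can add variation at low levels. RMA gives no detection call.

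Probe sets were named from the platform annotation, which can be old. Of the 45101 probe sets, 64 were Affymetrix controls, 34945 had 1 gene symbol, 932 had several and 9160 were not listed in the annotation table and stay unnamed. Gene identifiers of 34741 probe sets were found in a mouse RefSeq gene table (GRCm38.p6), which changed 0 symbols and was used for names alone. Each of 18193 genes was represented by its probe set with the highest mean over the 6 arrays, a choice that matters for the 9010 genes with more than 1 probe set. No per-sample column was left unmapped and 0 values were missing. The background level of 4.60 is the 95th percentile of the mean log2 values of 71 olfactory and vomeronasal receptor genes, whose median was 2.70. Where the mean of 1 group lay below it, the fold was computed against the level and is given as a lower bound. A mean above the level can include single arrays below it.

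Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over all 18193 genes, threshold 0.05). Gene lists with at least 3 measured members were tested with camera at a preset correlation of 0.01, adjusted over 20 lists, with camera at an estimated correlation and fry beside it. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The test, the lists, the background level and the alternatives were fixed before the data were examined. The text names Cck, Ildr1, Ildr2 and Lsr, the 12 genes with the largest positive and the 12 with the largest negative difference among those past the threshold whose groups did not overlap, each measured gut hormone and receptor gene, and from each other list up to 4 members past the threshold by size of difference and up to 2 not past it by mean level. The 21 lists covered gut hormones, granule and prohormone processing, enteroendocrine transcription factors, regulated exocytosis, nutrient and hormone receptors, ion channels and monoamine transport, angulins and tight junctions, and markers of enterocytes, goblet, Paneth, tuft, stem and crypt-base cells, cell cycle, T and NK lymphocytes, B and plasma cells, myeloid cells and antigen presentation, stroma and endothelium, enteric neurons and glia, pancreatic acinar cells, erythroid cells and the dissociation response. Of their members 240 were measured and 36 are not analysed here.

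Alternatives were the replicate number as a block, 2 filters on dim genes (the background level, and the lowest 25% of genes), eBayes with trend and robust settings, array weights, centring each array on its median, a second quantile normalization, the mean of all probe sets of a gene, each probe set tested alone, a test against a difference of 0.5 on the log2 scale (treat), and leaving out each array in turn. The labels number the samples 1 to 3 in both groups without saying what a number marks. Across genes, which are not independent replicates, the deviations of arrays from their group means were correlated. The values were 0.242, 0.197 and 0.198 between arrays of the same number and -0.188 to -0.0404 between other numbers. Deviations cancel within a group, so the negative values follow from the positive ones. As each same-number pair was above 0.1, the numbers were taken to pair the samples. The main test had been fixed without a block and does not use this pairing. Calls that change with the replicate number as a block are given beside the results.

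Between the 3' and 5' control probe sets of beta-actin the log2 difference was 1.03 to 1.71, and for Gapdh 1.42 to 1.78. The transferrin receptor control differed by 1.17 on non-EGFP replicate 1 and by 2.89 to 3.76 on the other arrays. The pyruvate carboxylase control, Pcx, differed by 2.36 to 3.07 on the CCK-EGFP arrays and by 4.26 to 4.38 on the non-EGFP arrays, with its 5' set between 4.72 and 5.96, near the background level. No arrays held identical values. The procedure was tested on simulated data made from these arrays, with 200 of 18193 genes changed in each of 5 simulations. It recovered 8.36% of genes with a true log2 difference of 1, 70.8% at 2 and 95.1% at 4, and 5.25% of its calls were unchanged genes. The shifted list passed camera in 5 of 5 simulations, and 0 of 95 unshifted lists did. Noise was drawn independently for each gene, so the list result does not cover genes that vary together. Far fewer genes were changed than the 4391 called in the data, so the recovery rates need not carry over.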

Results

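Gene expression was measured on 6 Affymetrix mouse arrays, 3 of intestinal cells sorted for enhanced green fluorescent protein (EGFP) and 3 of non-fluorescent intestinal cells taken in equal number. The donors were adult Swiss Webster mice carrying a transgene in which EGFP marks cells that express cholecystokinin (Cck), the hormone of enteroendocrine I cells that is released after a fatty meal. The comparison asks which genes these CCK-EGFP cells express above or below other intestinal cells, and the series title names Ildr1, an immunoglobulin-like domain receptor, in relation to fat-stimulated cholecystokinin secretion. Values are log2 RMA intensities, where 1 unit is a doubling, and array medians ran from 5.66 to 5.72 in CCK-EGFP cells and from 5.37 to 5.55 in non-EGFP cells. Olfactory and vomeronasal receptor genes served as a measure of background. The 95th percentile of their means, 4.60, was taken as the background level, and 12975 of the 18193 genes measured (71.3%) had a mean above it. The labels do not state whether the 3 samples of a group came from separate mice, so p-values measure the spread between these samples, which may be technical, and 3 arrays per group limit the precision.

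The arrays separated by group. The first principal component held 63.2% of the variance and placed the CCK-EGFP arrays between -135 and -94.2 and the non-EGFP arrays between 98.6 and 142. Pearson correlations across probe sets were 0.969 to 0.981 within CCK-EGFP cells, 0.952 to 0.962 within non-EGFP cells and 0.879 to 0.933 between the groups. CCK-EGFP replicate 3 lay nearest the non-EGFP arrays on that component, and its mean enterocyte marker level was 12.77 against 11.89 and 12.02 in the other CCK-EGFP arrays. Of the controls for RNA quality, Pcx parted the groups. The 3' minus 5' log2 difference of its control probe sets was 2.36, 2.45 and 3.07 on the CCK-EGFP arrays and 4.26, 4.38 and 4.26 on the non-EGFP arrays, and Pcx itself, singled out after its values were seen, was lower in CCK-EGFP cells (log2 difference -2.68, limma adjusted p = 0.0013). The controls for beta-actin, Gapdh and the transferrin receptor overlapped between the groups.

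Cck itself, the gene that marks the sorted cells, was 23.2-fold higher in CCK-EGFP cells, at 13.16 ± 0.32 (SD, n = 3) against 8.63 ± 0.27 (log2 difference 4.53, SE 0.25, limma with Benjamini-Hochberg adjusted p = 0.000192). Ildr1 averaged 6.97 ± 0.19 in CCK-EGFP cells and 3.14 ± 0.24, below the background level, in non-EGFP cells. Each of these genes has 1 probe set on the array. Its log2 difference was 3.83 (SE 0.21, limma adjusted p = 0.000194), and against the background level it was at least 5.17-fold higher. The other angulins, the family of tricellular junction proteins to which Ildr1 belongs, did not pass the test. Lsr was abundant in both groups, at 11.67 ± 0.22 and 11.11 ± 0.13 (log2 difference 0.55, SE 0.20, adjusted p = 0.0868), and its 2 probe sets differed in sign, at -0.43 and 0.55. Ildr2 was near background in both, at 3.80 ± 0.10 and 4.25 ± 0.21 (adjusted p = 0.128).

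**Figure D1:**
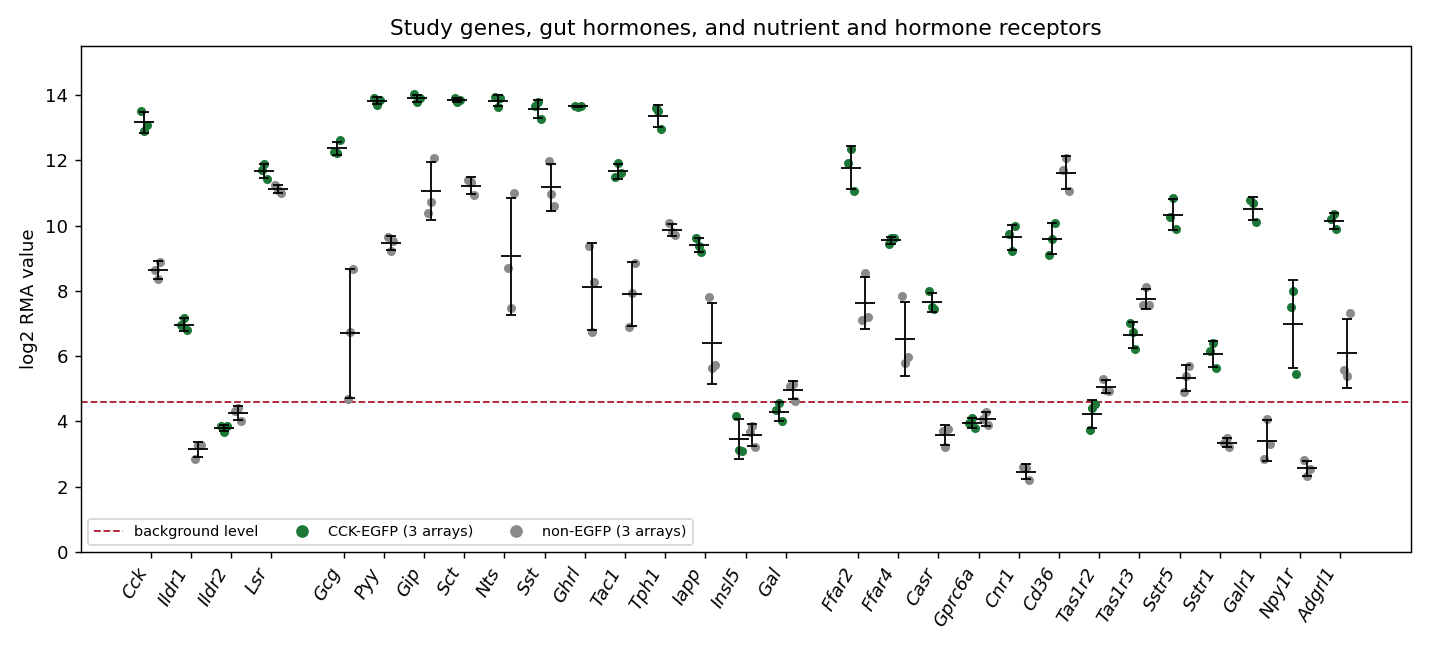
Log2 RMA value (vertical axis) of Cck, Ildr1, Ildr2, Lsr, the gut hormone genes and the nutrient and hormone receptor genes on each of the 6 arrays, with the mean and SD of each group of 3 and the background level of 4.60 as a dashed line. Cck averaged 13.16 in CCK-EGFP and 8.63 in non-EGFP cells, and Ildr1 averaged 6.97 and 3.14, the latter below the dashed line.

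Across all genes, 2540 were higher and 1851 lower in CCK-EGFP cells (limma, adjusted p under 0.05), and the higher ones went much further. With group means below the background level raised to it, 623 of those past the threshold were higher and 23 lower by at least 3 on the log2 scale, and 106 were higher and 0 lower by at least 5. Among 202 genes with a non-EGFP mean above 13, the largest fall was -1.94. Saturation at high levels and carried-over non-fluorescent cells can limit falls, and neither was tested as a cause of this imbalance. Lpl, which encodes lipoprotein lipase, stood at 11.89 ± 0.42 against 3.07 ± 0.58, below the background level, and was at least 157-fold higher (fitted log2 difference 8.82, SE 0.36, adjusted p = 0.000104). Among genes with means above that level in both groups, Sphkap was higher by 7.63, the granule protein Scg2 by 7.56, the calcium-binding protein Scgn by 7.42 and the G protein regulator Rgs4 by 7.15. On the non-EGFP arrays Scgn read 4.26, 4.30 and 6.06 and Rgs4 read 6.59, 3.74 and 4.20, so each mean passed the level through a single array. Against the background level, the protease inhibitor Pzp was at least 93.2-fold higher, Klhl13 at least 60.7-fold, the vesicle priming factor Cadps at least 58.4-fold, the cytochrome P450 Cyp2j5 at least 55.0-fold, the G protein subunit Gnai1 at least 53.7-fold, the sodium-calcium exchanger Slc8a1 at least 35.6-fold and the cannabinoid receptor Cnr1 at least 32.9-fold. Adjusted p-values of these genes were at most 0.00147. Where a gene had several probe sets, the lowest difference was -0.41 for Slc8a1, 1.10 for Sphkap and 1.12 for Cnr1. It was 2.99 for Gnai1, 3.44 for Rgs4, and at least 3.57 for Klhl13, Cyp2j5 and Lpl.

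Genes lower in CCK-EGFP cells included Slc5a8, a monocarboxylate transporter, at 3.71 ± 0.97 against 8.33 ± 0.64, at least 13.3-fold lower by the background level (fitted log2 difference -4.62, SE 0.55, limma adjusted p = 0.00273). Tmprss15, which encodes enteropeptidase, differed by -3.52 (adjusted p = 0.00327), Slc4a11 by -3.46, the tropomyosin Tpm2 by -3.46, the glucuronosyltransferase Ugt2b38 by -3.44 and the cytochrome P450 Cyp2a12 by -3.40. Plscr2 was at least 6.28-fold and Thegl at least 4.59-fold lower by the background level. The smallest falls among the probe sets of Slc4a11, Tpm2 and Thegl were -0.66, -0.75 and -0.32. Nyx (at least 13.9-fold lower), Them7 (-3.81), Pramel29 (at least 8.28-fold lower) and the chemokine gene Ccl24 (-3.35) were also called, and these 4 depended on single arrays. The calls of Nyx and Pramel29 ended without CCK-EGFP replicate 2 (adjusted p = 0.0525 and 0.057). Them7 lost its call without CCK-EGFP replicate 1 or 3 or non-EGFP replicate 2 or 3 (adjusted p up to 0.106), and Ccl24 lost it without CCK-EGFP replicate 1 or 3 or non-EGFP replicate 1 or 2 (up to 0.0634). With each array centred on its median the split of calls was 2102 higher and 3611 lower, against 2540 and 1851 as deposited. Of the 1851 lower genes, 181 had both means below the background level, against 25 of the higher ones.

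The sorted CCK-EGFP cells, measured as a pool, carried higher levels of many gut hormone transcripts besides Cck. In a pool, several hormones in the same cell cannot be told from a mixture of cells. Of 13 measured gut hormone genes, 11 were higher, 0 lower and 2 did not pass (adjusted over the list alone, 11 higher and 1 lower), with a median log2 difference of 3.48. The list passed camera with a preset correlation (adjusted p = 1.65e-07) but not with an estimated one (adjusted p = 0.0532 with an estimated correlation). These counts include Cck, the gene the cells were sorted on. Without it, an alternative chosen after seeing the data, 10 of 12 were higher and 0 lower, with a median of 3.24 and camera adjusted p = 1.67e-06 (adjusted p = 0.0532 with an estimated correlation). Gcg, the precursor of glucagon-like peptides, was higher by 5.66 (SE 0.91, adjusted p = 0.00813), the ghrelin gene Ghrl by 5.52, the neurotensin gene Nts by 4.77, Pyy by 4.35, the tachykinin precursor Tac1 by 3.77, Tph1, the serotonin-synthesis enzyme, by 3.48, Iapp by 3.01, Gip by 2.84, secretin (Sct) by 2.63 and somatostatin (Sst) by 2.40. Several of these were abundant in non-EGFP cells as well, with Gip at 11.06 ± 0.89, Sct at 11.22 ± 0.26 and Sst at 11.17 ± 0.72. In CCK-EGFP cells Gip (13.90), Sct (13.85), Nts (13.83), Pyy (13.82), Ghrl (13.65) and Sst (13.57) lay toward the array maxima of 14.7. Saturation there can shrink a difference, so the order of these genes by size is uncertain. Insl5 was near background in both groups (3.46 ± 0.62 and 3.58 ± 0.34), and Gal stood at 4.30 ± 0.28 and 4.96 ± 0.28 (adjusted p = 0.0934). Iapp lost its call without CCK-EGFP replicate 1 or 2 (adjusted p up to 0.0579). The lowest probe set difference was 0.76 for Tac1 and 1.40 for Iapp.

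Every measured gene for secretory granules and prohormone processing was higher, 11 of 11 (11 adjusted over the list alone), with a median log2 difference of 4.93. Camera gave adjusted p = 1.9e-11 (adjusted p = 0.0532 with an estimated correlation). The granule proteins Scg2 (7.56), Vgf (6.64), Pcsk1n (5.54) and Resp18 (5.37) led the list, Scg2 rising from 5.46 ± 0.58 to 13.02 ± 0.09. Of 20 regulated exocytosis genes, 16 were higher, 0 lower and 4 did not pass (16 higher adjusted over the list alone), with a median of 3.40, or 3.35 with means below the background level raised to it. Camera gave adjusted p = 2.02e-11 (adjusted p = 0.102 with an estimated correlation). Among them were the syntaxin Stx1a (6.95), synaptophysin Syp (6.45), Cadps (at least 5.87 against the background level) and the synaptotagmin Syt13 (5.58), while Rims2 (0.65, adjusted p = 0.152) and Dnajc5 (-0.41, adjusted p = 0.158) did not pass. The probe sets of Syp ranged from -0.21 to 6.45, those of Rims2 from -0.05 to 2.53 and those of Dnajc5 from -1.52 to -0.07.

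Transcription factors of the enteroendocrine lineage were higher in 13 of 16 cases, 1 was lower and 2 did not pass (adjusted over the list alone, 14 higher and 1 lower), with a median of 3.56. The LIM factor Isl1 rose by 6.15, Pax6 by 5.98, Nkx2-2 by 5.83 and St18 by at least 5.20 against the background level (adjusted p at most 0.00156), and the probe sets of Pax6 ranged from -0.25 to 5.98. Pax6 read 4.59, 3.92 and 6.44 on the non-EGFP arrays, so its mean there passed the background level through a single array. Pax4 (2.90, adjusted p = 0.0589) and Neurod2 (1.24, adjusted p = 0.149) did not pass. The lower gene, singled out after its values were seen, was Neurog3, the factor of endocrine progenitors, at 3.75 ± 0.16 against 4.49 ± 0.17, both below the background level (log2 difference -0.73, adjusted p = 0.0379, or 0.0521 with the replicate number as a block), and its other probe set differed by 0.48. Ion channel and monoamine transporter genes were higher in 13 of 15 cases and lower in 0 (13 higher adjusted over the list alone), with a median of 3.49, or 3.16 with means below the background level raised to it. They included the calcium channel subunit Cacna2d1 (6.95), the irritant-sensing channel Trpa1 (5.79), the sulfonylurea receptor Abcc8 (5.40) and Trpc4 (at least 4.23 against the background level), whereas Cacna1d stood at 10.80 ± 0.16 and 10.87 ± 0.39 (adjusted p = 0.833) and Kcnk3 differed by 0.65 (adjusted p = 0.132). The lowest probe set difference was 1.67 for Cacna2d1 and 0.87 for Trpc4. The transcription factor and channel lists both passed camera (adjusted p = 2.34e-10 each). They were the only 2 of the 20 tested lists to pass with an estimated correlation (adjusted p = 0.0261 with an estimated correlation for each).

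Receptors for nutrients and hormones were mostly higher, 9 of 13, with 2 lower and 2 not past the threshold (adjusted over the list alone, 9 higher and 3 lower). The list median was 4.05, or 3.02 with means below the background level raised to it, with camera adjusted p = 0.000172 (adjusted p = 0.0969 with an estimated correlation). Increases were found for the somatostatin receptor Sstr5 (10.33 ± 0.48 against 5.33 ± 0.41), the short-chain fatty acid receptor Ffar2 (4.14), Adgrl1 (4.05) and the long-chain fatty acid receptor Ffar4 (3.02, SE 0.54, adjusted p = 0.0113). Where the non-EGFP mean was below the background level, the increase against that level was at least 5.92 for the galanin receptor Galr1, 5.04 for Cnr1, 3.05 for the calcium-sensing receptor Casr, 2.39 for Npy1r and 1.47 for the somatostatin receptor Sstr1. Ffar4 stood at 9.55 ± 0.10 in CCK-EGFP cells and 6.54 ± 1.13 in non-EGFP cells. Cd36, a fatty acid transporter, fell by 2.03 (9.59 ± 0.48 against 11.62 ± 0.51, adjusted p = 0.0105). The sweet and umami receptor subunit Tas1r3 fell by 1.09 (adjusted p = 0.0352), a call that ended when any 1 of the 6 arrays was left out (adjusted p up to 0.0993). Tas1r2 was near background in CCK-EGFP cells (4.22 ± 0.43 against 5.07 ± 0.21, adjusted p = 0.065), as was Gprc6a in both groups. For Galr1, Npy1r and Casr the probe sets disagreed, with lowest differences of -0.67, -0.05 and 0.05, and the lowest of Cnr1 was 1.12.

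**Figure D2:**
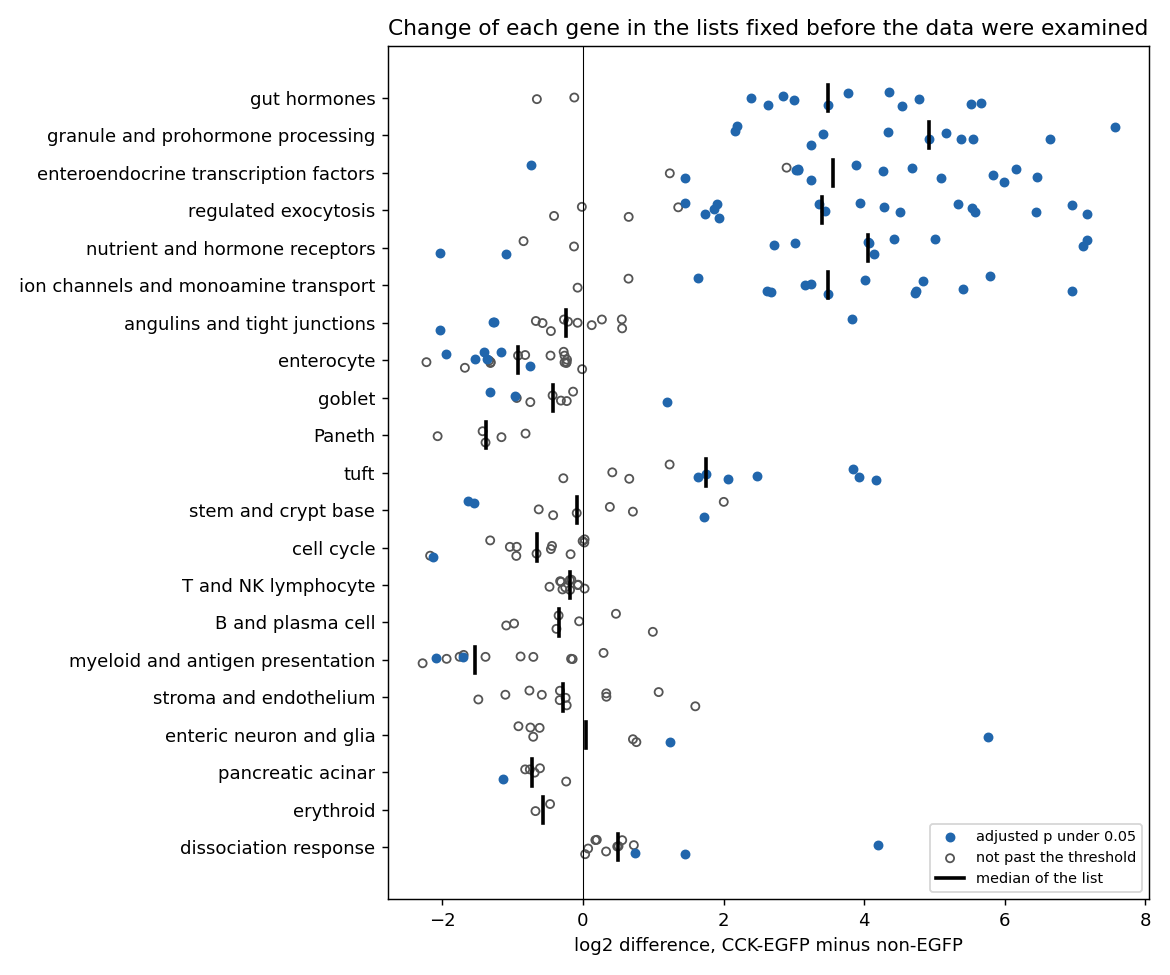
Log2 difference, CCK-EGFP minus non-EGFP (1 point per measured gene, filled where the limma adjusted p was under 0.05), by gene list, with the median of each list as a black bar and differences as fitted, also where a group mean lay below the background level. Granule genes had a median of 4.93 and gut hormones of 3.48, whereas enterocyte markers had a median of -0.92 and T and NK lymphocyte markers of -0.19.

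Genes of angulins and tight junctions showed no common direction. Of 14 measured, 1 was higher, Ildr1, 3 were lower and 10 did not pass (the same counts adjusted over the list alone), with a median of -0.24, or -0.14 with means below the background level raised to it, and camera adjusted p = 0.563 (adjusted p = 0.807 with an estimated correlation). The lower genes were the claudin Cldn15 (-2.04, adjusted p = 0.0326), Tjp3 (-1.28, adjusted p = 0.00447) and cingulin Cgn (-1.27, adjusted p = 0.0125). Cldn7 (13.13 ± 0.10 and 13.20 ± 0.09) and Cldn3 (11.91 ± 0.22 and 12.13 ± 0.19) did not pass (adjusted p = 0.758 and 0.461).

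Some enterocyte markers were lower in CCK-EGFP cells. Of 21, 0 were higher, 6 lower and 15 did not pass (adjusted over the list alone, 0 higher and 9 lower), with a median of -0.92. Camera gave adjusted p = 0.000442 for the list (adjusted p = 0.632 with an estimated correlation). The brush border enzyme Treh fell by 1.94 (adjusted p = 0.0341), the lipoprotein assembly factor Mttp by 1.53, the sodium-glucose transporter Slc5a1 by 1.40 and the triglyceride-synthesis enzyme Dgat2 by 1.36. Apoa1 (14.36 ± 0.01 and 14.37 ± 0.08) and Apoa4 (14.07 ± 0.22 and 14.29 ± 0.05) did not pass (adjusted p = 0.968 and 0.392), but both lay near the array maxima of 14.7 to 14.8, where saturation can hide a difference. The calls of Treh, Mttp, Slc5a1 and Cldn15 each ended when any array other than CCK-EGFP replicate 3 was left out (adjusted p up to 0.111, 0.126, 0.131 and 0.104), and that of Dgat2 ended without CCK-EGFP replicate 2 (0.0502). With the replicate number as a block, Treh (0.0527) and Mttp (0.055) did not pass, other markers of the list gained a call, and 5 were lower.

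Goblet markers went both ways. Of 9 goblet markers, 1 was higher, 2 lower and 6 not past the threshold (adjusted over the list alone, 1 and 4), with camera adjusted p = 0.199 (0.749 as adjusted p with an estimated correlation). Agr2, a protein-folding enzyme of secretory cells, rose by 1.20 (adjusted p = 0.00655), while the mucin Muc2 fell by 1.33 (adjusted p = 0.0473) and the factor Spdef by 0.97 (adjusted p = 0.0205). Tff3 (13.92 ± 0.09 and 14.06 ± 0.07) and Zg16 (13.89 ± 0.17 and 14.12 ± 0.04) did not pass, but both lay high on the scale, where saturation can hide a difference. Muc2 lost its call without any array but CCK-EGFP replicate 3 (adjusted p up to 0.114), and Spdef without any CCK-EGFP array or non-EGFP replicate 1 (up to 0.0714). None of the 5 Paneth markers passed in limma, 0 also at an unadjusted p under 0.05 and 0 adjusted over the list alone (Lyz1 at 12.22 ± 0.93 and 13.03 ± 0.49, Itln1 at 10.49 ± 0.95 and 11.64 ± 0.78). With the replicate number as a block 4 of the 5 were lower, Itln1 among them (adjusted p = 0.0247). The camera adjusted p of the list went from 0.224 to 0.00796 (adjusted p = 0.807 with an estimated correlation and no block). Without the block, the Paneth list passed camera when CCK-EGFP replicate 3 was left out (adjusted p = 0.016).

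Among 9 stem and crypt-base markers, Axin2, a target of Wnt signalling, was higher by 1.73 (adjusted p = 0.00608), Cdca7 was lower by -1.64 (adjusted p = 0.0389) and Rnf43 by -1.54 (adjusted p = 0.0208), and 6 did not pass, Olfm4 (6.86 ± 2.02 and 7.28 ± 2.54) and Slc12a2 (10.21 ± 0.25 and 9.50 ± 0.56) among them. The list had a median of -0.09 (0 with means below the background level raised to it), a mean of 0.06 and camera adjusted p = 0.805 (adjusted p = 0.914 with an estimated correlation), and adjusted over the list alone 2 were higher and 2 lower. The probe sets of Axin2 ranged from 0.10 to 1.73 and those of Cdca7 from -1.64 to 0.20. Rnf43 lost its call without non-EGFP replicate 2 (adjusted p = 0.0611), and Cdca7 without CCK-EGFP replicate 1 or 2 or non-EGFP replicate 2 or 3 (up to 0.124). Of 13 cell cycle genes, 0 were higher and 1 was lower, Ube2c, by -2.13 (adjusted p = 0.0439), and adjusted over the list alone 0 passed. Pcna stood at 10.80 ± 0.27 and 10.77 ± 0.17. The call of Ube2c ended without any array but CCK-EGFP replicate 3 (up to 0.136). With the replicate number as a block 3 cell cycle genes were lower, Birc5 among them (adjusted p = 0.0433 against 0.555). The camera adjusted p of the list went from 0.255 to 0.046 (adjusted p = 0.807 with an estimated correlation and no block). Without the block, the cell cycle list passed camera when CCK-EGFP replicate 3 (adjusted p = 0.0159) or non-EGFP replicate 1 (0.0426) was left out.

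Several tuft cell markers were higher in CCK-EGFP cells. Of 11, 7 were higher, 0 lower and 4 did not pass (7 higher adjusted over the list alone), with a median of 1.76. Camera gave adjusted p = 0.000102 (adjusted p = 0.352 with an estimated correlation). Dclk1 rose by at least 4.14 against the background level (SE of the fitted difference 0.61, adjusted p = 0.00592), Siglecf by 3.92, Sh2d6 by 3.84 and the actin-binding protein Avil by 2.47. Trpm5, the taste-transduction channel, stood at 10.07 ± 0.48 and 9.41 ± 0.32 (adjusted p = 0.156), and Ltc4s at 7.12 ± 0.48 and 7.39 ± 0.85 (adjusted p = 0.67). The 9 probe sets of Dclk1 ranged from -0.06 to 4.16.

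Lymphocyte markers were strong in both sorted populations. None of 11 T and NK lymphocyte markers passed in limma (0 at an unadjusted p under 0.05, 0 adjusted over the list alone), with a median difference of -0.19, or -0.44 with each array centred on its median, and camera adjusted p = 0.805 (adjusted p = 0.967 with an estimated correlation). The granzyme gene Gzma was at 12.36 ± 0.49 and 12.34 ± 0.59, and the chemokine gene Ccl5 at 12.29 ± 0.76 and 12.36 ± 0.49. The mean of the list on CCK-EGFP replicates 1, 2 and 3 was 9.64, 10.71 and 11.89, and on the non-EGFP replicates of the same numbers 10.28, 10.90 and 11.69. None of 7 B and plasma cell markers passed either (0 at an unadjusted p under 0.05, 0 adjusted over the list alone, camera adjusted p = 0.925, and adjusted p = 0.967 with an estimated correlation), with Jchain at 9.73 ± 1.78 and 9.78 ± 1.20 and Pou2af1 at 7.12 ± 1.38 and 8.21 ± 1.38.

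Of 12 myeloid and antigen-presentation genes, 2 were lower, the class II gene H2-Eb1 by -2.09 (adjusted p = 0.0244) and the complement gene C1qb by -1.70 (adjusted p = 0.0135), and 10 did not pass (adjusted over the list alone, 2 lower), Cd74 (12.30 ± 0.84 and 13.69 ± 0.21) and H2-Aa (9.95 ± 1.64 and 12.23 ± 0.58) among them. Its camera adjusted p was 0.0254 (adjusted p = 0.717 with an estimated correlation), and without CCK-EGFP replicate 1 or non-EGFP replicate 3 it was 0.0624 and 0.109. H2-Eb1 lost its call without CCK-EGFP replicate 2 or non-EGFP replicate 2 or 3 (adjusted p up to 0.0825). With the replicate number as a block 5 genes of the list were lower, H2-Aa among them (adjusted p = 0.0358).

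**Figure D3:**
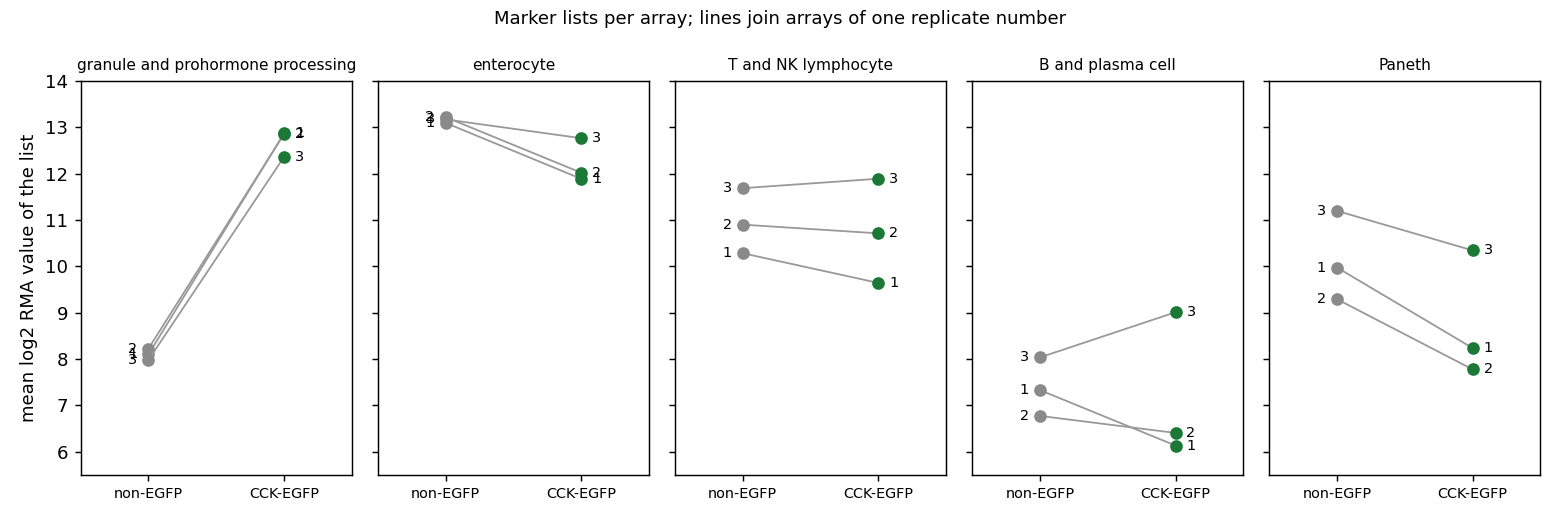
Mean log2 RMA value (vertical axis) of the measured members of 5 gene lists on each array, by group, with a line joining the arrays of the same replicate number. Lymphocyte markers ran from 9.64 to 11.89 in CCK-EGFP and from 10.28 to 11.69 in non-EGFP cells, while enterocyte markers ran from 11.89 to 12.77 and from 13.10 to 13.22.

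Few markers of stroma, nerve, pancreas or blood passed the test. None of 12 stromal and endothelial markers passed in limma (1 higher and 2 lower at an unadjusted p under 0.05, 0 adjusted over the list alone, camera adjusted p = 0.654, and adjusted p = 0.807 with an estimated correlation), with Vim at 11.05 ± 1.02 and 9.97 ± 0.15 and Tagln at 6.45 ± 0.44 and 7.94 ± 1.24. Of these 12 markers, 7 had both means below the background level, where a difference can hardly be found. Of 8 enteric neuron and glia markers 2 were higher (adjusted over the list alone, 2 higher and 1 lower), the tyrosine hydroxylase gene Th by at least 5.45 against the background level (adjusted p = 0.00188) and Gfap (adjusted p = 0.0149), which reached 4.69 ± 0.37, close to the background level, against 3.45 ± 0.14. Sox10 (-0.92 as fitted, -0.69 against the background level, adjusted p = 0.0557) and Tubb3 (0.71, adjusted p = 0.112) did not pass, nor did the list (camera adjusted p = 0.654, and adjusted p = 0.807 with an estimated correlation). The probe sets of Gfap ranged from -0.40 to 1.25. Gfap lost its call without CCK-EGFP replicate 1 or 2 (adjusted p up to 0.0655). Of 6 pancreatic acinar genes 1 was lower, the trypsinogen Prss2 (-1.14 as fitted, -0.43 against the background level, adjusted p = 0.022). Adjusted over the list alone 4 were lower (camera adjusted p = 0.0754, and adjusted p = 0.3 with an estimated correlation). All means of Prss2, Cela3b and Cela2a were below 6, and 3 of the 6 genes had both means below the background level. Prss2 lost its call without any array but non-EGFP replicate 3 (adjusted p up to 0.0663). The pancreatic list passed camera without non-EGFP replicate 1 (adjusted p = 0.0427). Both erythroid genes measured, Alas2 (7.44 ± 1.94 and 8.11 ± 2.58) and Hba-a1 (3.10 ± 0.04 and 3.56 ± 0.42), did not pass (adjusted p = 0.745 and 0.203).

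Few genes that respond to tissue dissociation passed the test. Of 12, 3 were higher in CCK-EGFP cells, 0 lower and 9 did not pass (3 higher adjusted over the list alone), with a median of 0.50, or 0.25 with each array centred on its median. Camera gave adjusted p = 0.0202 for the list (adjusted p = 0.717 with an estimated correlation). The nuclear receptor Nr4a1 rose by 4.20 (SE 0.41, adjusted p = 0.00136), Ier2 by 1.45 (adjusted p = 0.0204) and Egr1 by 0.74 (adjusted p = 0.0432, or 0.0599 with the replicate number as a block). Fos (13.55 ± 0.14 and 13.48 ± 0.08) and Dusp1 (13.17 ± 0.31 and 12.61 ± 0.30) did not pass, and at the level of Fos saturation can hide a difference. The list's call ended without CCK-EGFP replicate 1 (adjusted p = 0.0624), non-EGFP replicate 2 (0.0807) or non-EGFP replicate 3 (0.0836), over genes above the background level alone (0.112), with the lowest 25% of genes left out (0.089) and in fry (0.118). Ier2 lost its call without CCK-EGFP replicate 1 or 2 or non-EGFP replicate 2 (adjusted p up to 0.0622), and Egr1 without any array but non-EGFP replicate 1 (up to 0.135).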

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

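Cck (4.28 to 4.66) and Ildr1 (3.57 to 3.91) kept their direction and their calls under every alternative run. Of the 86 named genes past the threshold, 65 kept it in all 6 fits without 1 array, 21 lost it in at least 1, and no named gene that passed changed sign in any alternative. Centring each array on its median moved the median difference of all genes from -0.17 to -0.42 and the lower calls from 1851 to 3611, with 2102 higher, so small falls are not separable from scaling. The cause was not tested. Under it the median of enteric neuron and glia markers went from 0.05 to -0.20, and under a second quantile normalization that of stem and crypt-base markers went from -0.09 to 0.04, and the other list medians kept their sign. A test against a difference of 0.5 left 1487 higher and 487 lower, since it asks for more than a difference from 0, and ended the calls of 18 named genes. Without 1 array, a fit of fewer samples, the higher calls ran from 1365 to 2486 and the lower from 505 to 1962. Higher calls were 1468 without CCK-EGFP replicate 1 and 1365 without replicate 2. Lower calls were 666 and 505 without these, 1021 without non-EGFP replicate 1 and 880 without non-EGFP replicate 2. With the replicate number as a block 2340 genes were higher and 1534 lower, of which 2148 and 1273 were also called without it. The block ended the calls of Apob (0.068) and the tuft marker Gfi1b (0.0581), both singled out after their values were seen. Beyond these and those given beside the results it changed no other call among the named genes and no other camera result of a list. It also added calls among list members not named here. With it 5 enterocyte markers were lower (6 without it) and 2 stem and crypt-base markers were higher (1 without it).

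Of the 20 lists, 10 passed camera, and 2 passed with an estimated correlation (8 to 12 under the other alternatives, fry among them). In fry, which asks whether a list's genes move one way, the enterocyte list had adjusted p = 0.038, the pancreatic list 0.00126, the myeloid list 0.161 and the dissociation list 0.118. Under a second quantile normalization Egr1 (0.0524), Slc5a1 (0.0557) and Muc2 (0.0506) lost their calls, centring ended that of Egr1 (0.137), trend and robust settings that of Tas1r3 (0.0635), and the mean of probe sets those of Cdca7 (0.164), Gfap (0.283) and Prss2 (0.0704). Testing each of 34945 probe sets gave 2699 genes with a higher and 2229 with a lower probe set, 20 of them with both. Of the 10 splits of the 6 arrays into 3 and 3, 1, the real one, called 4391 genes or more, and the highest of the other 9 called 0 in limma (at most 755 at an unadjusted p under 0.05, and at most 378 in the splits that, like the real one, part all 3 pairs). Each of the other 9 splits mixes the groups, so the group difference enters its residual spread and few calls could be found. With 10 splits no share under 0.05 is possible, so the splits cannot decide whether a random grouping would do as well. Signal over background limits the low end, where 5218 genes had a mean at or below the background level.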

Other observations

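Apart from the calls of single genes and the tuft and lymphocyte list tests, which were planned, the tests in this part were chosen after the data were seen. A bound is the median with group means below the background level raised to it. Gene groups outside the lists fixed beforehand, picked by symbol among genes above the background level, were tested as 6 lists, and their p-values are adjusted over these 6 alone, without their selection. A search of 151 families of symbols with the same leading letters found 0 past the threshold with either correlation in camera (24 families at an unadjusted p under 0.05). Of 39 genes of ciliary transport, 22 were higher and 4 lower in CCK-EGFP cells, with a median log2 difference of 1.62 (bound 1.55, camera adjusted p = 3.89e-05, and adjusted p = 0.0744 with an estimated correlation). Ift81 rose by 3.47, and against the background level Ift122 rose by at least 3.15 (limma adjusted p = 0.00016) and the Bardet-Biedl gene Bbs1 by at least 2.01. The 3 probe sets of Ift81 ranged from -0.15 to 3.47. Flagellar and axonemal genes, which build motile cilia, were higher in 16 and lower in 3 of 32 cases (median 1.34, bound 1.26, camera adjusted p = 0.0169, and adjusted p = 0.125 with an estimated correlation), led by the tektin Tekt2 at 10.44 ± 0.15 against 3.74 ± 0.45 and the dynein Dnah9 (at least 3.86 against the background level). Of 15 imprinted genes, 10 were higher and 0 lower, with a median of 2.49 (bound 1.96, camera adjusted p = 0.000448, and adjusted p = 0.0968 with an estimated correlation). Peg3 rose from 6.62 ± 1.15 to 13.08 ± 0.05, Nap1l5 by 4.59 and Plagl1 by at least 3.26 against the background level, and the probe sets of Peg3 ranged from -0.04 to 6.45 and those of Plagl1 from 0.03 to 5.60.

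Genes of xenobiotic and sterol metabolism went the other way, 35 of 74 lower and 6 higher, with a median of -1.08 (bound -1.06, camera adjusted p = 1.44e-07, and adjusted p = 0.125 with an estimated correlation). Ugt2b38 (-3.44), Cyp2a12 (-3.40) and Cyp3a44 (at least 4.92-fold by the background level) were lower, while Cyp2j5, Cyp2f2 and Gsto2 were at least 55.0-fold, 16.6-fold and 14.4-fold higher. Of 40 G protein subunits and regulators 14 were higher and 4 lower (median 0.81, bound 0.68, camera adjusted p = 0.0169, and adjusted p = 0.125 with an estimated correlation), with Gnai1, Rgs4, Gng4 (6.66) and Gnaz (4.87) at the head, and the 3 probe sets of Gng4 ranged from -0.53 to 6.66. Of 280 zinc finger genes named Zfp, 69 were higher and 8 lower, and the median was 0.46 (bound 0.46), or 0.21 with each array centred on its median. Camera gave adjusted p = 0.00715 over the 6 lists (adjusted p = 0.125 with an estimated correlation) but adjusted p = 0.114 over the 151 families (adjusted p = 0.896 with an estimated correlation).

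T and NK lymphocyte markers did not pass between the sorted populations, with a median of -0.19, or -0.44 with each array centred on its median, at non-EGFP levels of 9.61 to 12.36. Compression of high signals is argued against, since 29.0% of the 3978 genes at those levels were called (858 lower, 295 higher). Non-fluorescent cells carried over in their own proportions are argued against as the sole cause, but not excluded. The lymphocyte minus enterocyte difference was negative on all 6 arrays. It was 0.73 (SD 0.25 over 3 pairs) closer to 0 on the CCK-EGFP arrays than on the non-EGFP arrays. Both list changes were known when this comparison was chosen. The enterocyte list did not pass camera with an estimated correlation (adjusted p = 0.632). A cell preparation shared by arrays of the same number stays open. Pairing by number gave the smallest summed difference of the lymphocyte mean among the 6 possible pairings (1.03 against 1.89 for the next). An arbitrary numbering would do so in 1 of 6 cases, so this result cannot decide. The sort should remove lymphocytes from the CCK-EGFP cells, and no biological explanation was tested.

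Of 11 tuft markers 7 were higher in CCK-EGFP cells, a list call that was lost in camera with an estimated correlation (adjusted p = 0.352 with an estimated correlation), and a larger share of tuft cells is a candidate explanation. As the sole cause it would raise the markers alike, provided no other cells added signal for them. Of the 10 markers above background, 5 had 95% intervals that left out the list's median of 1.76. Dclk1 (4.16 as fitted, at least 4.14 against the background level) and Ltc4s (-0.28) were the farthest apart. Signal of these genes from other cells was not measured, so this result cannot decide on a larger tuft share. Tuft cells as all or a part of the difference, and expression of these genes in the CCK-EGFP cells themselves, stay open.

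Of the genes called lower, 181 had both means below the background level, where a higher floor on the non-EGFP arrays may produce them. Olfactory and vomeronasal receptor genes, 71 in all, were lower in CCK-EGFP arrays in 94.4% of cases (67 genes), with a median of -0.35, although 0 were called in limma (12 lower at an unadjusted p under 0.05). Their medians were 2.59, 2.49 and 2.54 on the CCK-EGFP arrays and 3.20, 2.95 and 2.64 on the non-EGFP arrays. Over the 4609 genes with both means below the level the median was -0.37, and over those called lower it was -0.81, so the floor is a hypothesis for part of that difference and real falls among these genes stay open.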
